A study of Mus musculus with 6 samples.

How the data were processed

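Aortic RNA was sequenced from mice that carried a floxed Srf allele in 1 or both copies together with Itga8-CreERT2, a tamoxifen-inducible Cre recombinase driven from the locus of a smooth muscle integrin. Per the labels' protocols, the mice received 5 daily doses of 33 mg/kg tamoxifen, the aortae were taken 10 days after the last dose, and adventitia and endothelium were stripped before each aorta was frozen on its own. Libraries were made with a stranded poly(A) kit, per the labels. The deposited table holds raw whole-number counts per gene for 55453 genes and 5 libraries, 3 heterozygous and 2 homozygous, and its columns carry the names that the labels give those samples. The labels list 6 samples, and homozygous replicate 1 was not analysed here. The design text states that 1 homozygous sample was dropped as an outlier without naming it.

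Per the submitters' processing notes, fastp 0.20.0, STAR 2.7.0f and featureCounts of Subread 1.6.4 were used with the build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes may not have been told apart. Gene coordinates were taken from GENCODE mouse release 21 on GRCm38, whose gene names include 54586 of the 55453 symbols. Of the 18192 genes tested, 18033 matched a single gene there.

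Library totals ranged from 26177821 to 34311855 counts. Genes with low counts were removed by edgeR's filterByExpr, libraries were scaled by TMM, and 18192 genes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on group alone. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The biological coefficient of variation was 15.8%, with 3 residual and 4.01 prior degrees of freedom. Values are CPM, counts scaled to library size after TMM, with the SD over libraries, and log2 fold changes are homozygous over heterozygous with their standard error (SE). Each library came from a separately frozen aorta, and p-values measure the spread between these 5 samples. No pair of libraries agreed within sampling noise.

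The design, 34 gene lists, the named-gene rule and most alternatives were fixed before the data were examined. The 31 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over the lists. Under the rule, the genes named were Srf, up to 10 genes per direction with the largest changes past the threshold, up to 4 passing members of each list that passed camera (the 2 most abundant if none passed), up to 6 passing and the 2 most abundant other members of the contractile, actin, immediate-early and Srf-cofactor lists, the most abundant member of each marker list, and the 5 most abundant genes. Since no gene passed, genes past the threshold within a list alone, the largest changes called by DESeq2, a group of lipogenic genes and several single genes (Guca1b, H2-T24, Eln, Des, mt-Co1, mt-Rnr1, Gm26917 and Rn7sk among them) were added after their values were seen. A member of the contractile list is not reported here on its own, though the list tests include it.

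Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter or a stricter filter on low counts, a replicate block, a term for the numbers in the sample descriptions, omission of mitochondrially encoded genes, and each library left out in turn. For the number term, libraries whose numbers lie within 10 of a neighbour share a level. Its group contrast therefore rests on homozygous replicate 2 against heterozygous replicate 3 alone. Robust and newer quasi-likelihood fits, a crossed pairing, and omission of Rn7sk, Gm26917 and mitochondrial genes were added after the data were seen. On data simulated for this comparison over 18192 genes, edgeR recovered 3 of 50 genes changed 1.5-fold, 29 of 50 changed 2-fold and 47 of 50 changed 4-fold, and 9.79% of its calls were false. DESeq2 recovered 16, 32 and 46 of 50, and 19.5% of its calls were false. The simulation drew genes independently, without tissue differences shared by many genes, and changed only genes above a minimum mean count. Its rates may therefore not hold for the real libraries. For each named gene, the share of its transcript's 100-base words that also occur in transcripts of other genes was counted on both strands.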

Results

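RNA of aortae stripped of adventitia and endothelium, per the labels, was counted in poly(A) libraries from 3 heterozygous control mice and 2 homozygous conditional knockout mice. The comparison asks which transcripts differ when smooth muscle cells lose both copies of Srf, the gene of serum response factor, rather than 1 copy. The heterozygous libraries held 32142058, 34311855 and 26177821 counts (replicates 1, 2 and 3) and the homozygous libraries 27685188 and 31873243 (replicates 2 and 3).

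Srf itself (GRCm38 chromosome 17, 46548329 to 46556175, 7 exons) stood at 56.1, 64.4 and 68.3 CPM in the heterozygous and at 45.0 and 38.6 CPM in the homozygous libraries. Its log2 fold change was -0.59 (SE 0.122), with non-overlapping groups, and the edgeR adjusted p was 0.115. DESeq2 gave an adjusted p of 0.00373 and the fit with no low-count filter 0.00415, against 0.0965 to 0.543 in the other edgeR and limma-voom fits. Gene-level counts also take in exons outside a deletion, and the control already lacks 1 copy in recombined cells.

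Contractile genes of smooth muscle fell as a group in the homozygous libraries. The median log2 fold change of the 28 members tested was -0.63 (camera adjusted p = 1.7e-34; adjusted p = 0.0237 with an estimated correlation; fry adjusted p = 0.00134). Of 21 lists that passed camera, 4 also passed fry, and the other 17 had fry adjusted p from 0.0976 to 0.531. Of the 28 contractile genes, 24 were lower when adjusted over the list alone and 0 when adjusted over all genes, while DESeq2 called 22 lower. Acta2, smooth muscle actin, stood at 7844 ± 757 CPM in heterozygous (SD, n = 3) and 4205 ± 63.5 CPM in homozygous libraries (SD, n = 2), a log2 fold change of -0.90 (SE 0.133). Myh11, smooth muscle myosin heavy chain, was at 9105 ± 378 and 5325 ± 226 CPM, a log2 fold change of -0.77 (SE 0.121). Cnn1, calponin, gave -0.91 (SE 0.111), Kcnmb1, a subunit of the large-conductance potassium channel, -0.73 (SE 0.0883), and Synpo2 -0.78 (SE 0.109). Itga8, whose locus carries the Cre driver, gave -0.66 (SE 0.111). Des, desmin, gave 0.04 (SE 0.321), with libraries of the 2 groups overlapping, and its sign turned without heterozygous replicate 3 (-0.16) or homozygous replicate 3 (-0.35).

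**Figure D1:**
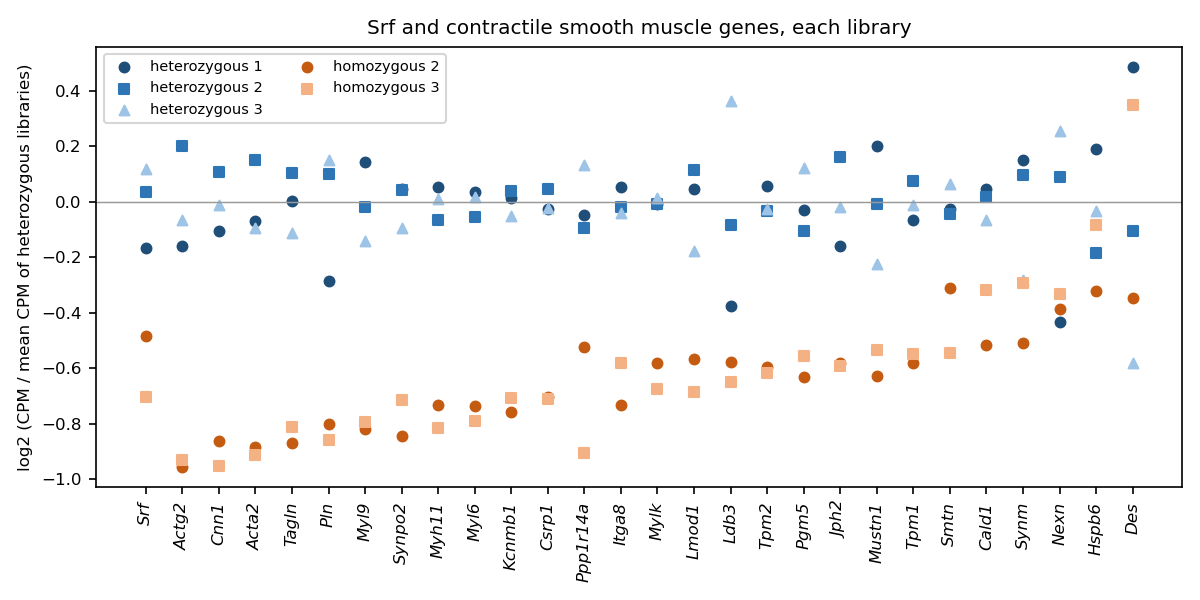
Each point is 1 library's CPM of Srf or of 1 of the contractile genes shown, as log2 of its ratio to the mean CPM of the 3 heterozygous libraries; blue marks heterozygous and orange homozygous libraries. Acta2, Cnn1 and Myh11 lie lower in both homozygous libraries than in every heterozygous library, while those of Des overlap.

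Genes of the actin cytoskeleton and cell adhesion fell as well, with a median log2 fold change of -0.53 over 26 members (camera adjusted p = 2.36e-18). The adjusted p was 0.214 with an estimated correlation and 0.0464 by fry. Adjusted over the list alone 20 were lower, against 0 adjusted over all genes and 15 by DESeq2. Flna, filamin A and among the 5 most abundant genes, stood at 18656 ± 1028 CPM in heterozygous (SD, n = 3) and 11068 ± 421 in homozygous libraries (SD, n = 2), a log2 fold change of -0.75 (SE 0.132). Actb gave -0.58 (SE 0.135), Vcl, vinculin, -0.66 (SE 0.114) and Tln1, talin, -0.57 (SE 0.106). Vcl shares 38.6% and Ilk 71.3% of their 100-base words with transcripts of other genes, so their values are uncertain.

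Signalling and matrix genes of the vessel wall were lower by smaller amounts. The list of vasoactive receptors and their downstream signalling fell by a median of 0.33 over 20 members (camera adjusted p = 0.00027; adjusted p = 0.29 with an estimated correlation), with 8 lower and 2 higher adjusted over the list alone and 0 over all genes. Rock1, a protein kinase of smooth muscle contraction, gave -0.85 (SE 0.189) and Ednrb, an endothelin receptor, 0.75 (SE 0.107). Calcium handling and ion channel genes fell by a median of 0.19 (camera adjusted p = 0.000807; adjusted p = 0.214 with an estimated correlation; fry adjusted p = 0.0464), with 6 of 20 lower adjusted over the list alone and 0 over all genes. Kcnab1, a potassium channel subunit, gave -0.90 (SE 0.148). The vasoactive median was -0.22 without homozygous replicate 2. Fibrillar and basement membrane genes fell by a median of 0.28 (camera adjusted p = 1.19e-05; adjusted p = 0.321 with an estimated correlation), with 5 of 24 lower adjusted over the list alone and 0 over all genes. Col18a1 gave -0.68 (SE 0.112). With a term for the label numbers the calls of the ion channel and matrix lists were lost (adjusted p = 0.142 and 0.229). The fit with that term compares only homozygous replicate 2 with heterozygous replicate 3, here and below. Eln, elastin, stood at 4678 ± 221 CPM in heterozygous (SD, n = 3) and 6189 ± 260 in homozygous libraries (SD, n = 2), while the elastic fibre list had a median of 0.00 (camera adjusted p = 0.869).

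Cofactors of serum response factor had a median of -0.12 over 10 members (camera adjusted p = 0.162). Csrp2, a LIM-domain protein, gave -0.70 (SE 0.164) and was the 1 member lower when adjusted over the list alone, against 0 over all genes. Myocd, myocardin, gave -0.39 (SE 0.243), mostly through heterozygous replicate 3. It stood at 259, 266 and 449 CPM in the heterozygous and at 244 and 250 CPM in the homozygous libraries. The immediate-early list, with Klf6 at -0.23 (SE 0.139) and Mcl1 at -0.07 (SE 0.105), had a median of -0.02 (camera adjusted p = 0.701). Klf6 stood at 262, 247 and 328 CPM in the heterozygous and at 233 and 243 CPM in the homozygous libraries. Mcl1 turned positive (0.053) without homozygous replicate 2, and the immediate-early list passed camera (adjusted p = 0.00726, median 0.041) without heterozygous replicate 3. The cofactor list passed too without that library (adjusted p = 0.046, median -0.025), while its median was -0.23 without homozygous replicate 2. The modulated smooth muscle list had a median of 0.14 (camera adjusted p = 0.91) and included Postn at -0.59 (SE 0.131), the 1 member lower adjusted over the list alone. The chondro-osteogenic list (-0.06, adjusted p = 0.521), the TGF-beta response list (-0.18, adjusted p = 0.274) and the unfolded protein response list (-0.08, adjusted p = 0.949) did not pass camera. The chondro-osteogenic list passed (adjusted p = 0.0115, median 0.026) without homozygous replicate 2, and the unfolded protein response list (adjusted p = 0.0137, median 0.20) without heterozygous replicate 2. The TGF-beta list passed without homozygous replicate 3 (adjusted p = 0.0314, median -0.28) and with the replicate block (adjusted p = 0.0311, median -0.28). Its median was -0.0070 without heterozygous replicate 3, -0.034 without homozygous replicate 2 and -0.088 without heterozygous replicate 2. A term for the label numbers brought calls for the TGF-beta list (adjusted p = 0.0109, median -0.35) and for the immediate-early list (adjusted p = 0.00119, median -0.26).

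Energy metabolism genes rose as groups. All 22 nuclear respiratory-chain genes were higher when adjusted over the list alone and 0 over all genes, with a median of 0.56 (camera adjusted p = 4.24e-19; adjusted p = 0.313 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, stood at 299 ± 55.2 CPM in heterozygous (SD, n = 3) and 480 ± 13.4 in homozygous libraries (SD, n = 2). The 7 tested mitochondrially encoded genes had a median of 0.59 (camera adjusted p = 4.78e-06; adjusted p = 0.321 with an estimated correlation), all higher adjusted over the list alone and 0 over all genes. Mitochondrially encoded RNA, ribosomal RNA included, took 3.95%, 4.38% and 5.71% of counts in heterozygous and 7.95% and 7.36% in homozygous libraries. Most of it was the ribosomal mt-Rnr2, at 2.68%, 2.97% and 3.82% in heterozygous and 5.44% and 5.15% in homozygous libraries. Among the heterozygous libraries, replicate 3 had the lowest mean log2 CPM of the nuclear list (6.26) and the highest of the mitochondrially encoded list (9.34). Within that group the lists thus did not move together. Glycolysis genes had a median of 0.41 (camera adjusted p = 0.000113; adjusted p = 0.321 with an estimated correlation), with 9 of 15 higher and 2 lower adjusted over the list alone and 0 over all genes. Aldoa, an aldolase, gave 0.63 (SE 0.124).

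Markers of fat moved in the same direction in these libraries. Adipocyte markers had a median of 0.65 over 12 members (camera adjusted p = 1.83e-12; adjusted p = 0.29 with an estimated correlation), 10 of them higher adjusted over the list alone and 0 over all genes. Brown adipocyte markers had a median of 1.19 over 8 members (camera adjusted p = 2.2e-11; adjusted p = 0.29 with an estimated correlation), all higher adjusted over the list alone and 0 over all genes. Ucp1, the uncoupling protein of brown fat, ranged from 87.5 to 337 CPM in heterozygous libraries and stood at 582 and 569 CPM in homozygous libraries. Fabp4, a fatty acid carrier of adipocytes, gave 0.84 (SE 0.191).

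Skeletal muscle markers had a median of 2.48 over 12 members (camera adjusted p = 3.12e-08; adjusted p = 0.321 with an estimated correlation), but 0 passed adjusted over the list alone or over all genes. Myh1, a fast myosin heavy chain, stood at 119, 64.5 and 0.318 CPM in the heterozygous and at 296 and 496 CPM in the homozygous libraries. Cardiomyocyte markers (median 1.14, adjusted p = 0.00488; adjusted p = 0.29 with an estimated correlation) and muscle isoforms of other tissues (0.53, adjusted p = 0.0429; adjusted p = 0.347 with an estimated correlation) also passed camera with 0 single members. Without homozygous replicate 3 both medians turned negative (-0.030 and -0.091), and the cardiomyocyte call was also lost with a term for the label numbers (0.17, adjusted p = 0.377). The muscle isoform median was 0.83 without heterozygous replicate 1 and 0.37, no longer called (adjusted p = 0.124), without heterozygous replicate 2. Without homozygous replicate 2 the cardiomyocyte median was 1.73 and the muscle isoform median 0.93, and without homozygous replicate 3 the skeletal muscle median was 1.59. Heterozygous replicate 3 stood apart on the first principal component, which held 51.6% of the variance. Heterozygous replicates 1, 2 and 3 stood at -1.66, 8.67 and 56.4 and homozygous replicates 2 and 3 at -20.5 and -42.9. From low to high, this is the order of the libraries, from most to least, in 10 of the 12 skeletal muscle markers. The component also separated the groups, so genotype and that tissue cannot be told apart on it.

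Inflammation and chemokine genes rose by a median of 0.71 over 16 members (camera adjusted p = 1.51e-06; adjusted p = 0.214 with an estimated correlation), with 9 higher adjusted over the list alone and 0 over all genes. C3, complement component 3, stood at 556 ± 66.3 CPM in heterozygous (SD, n = 3) and 967 ± 92.7 in homozygous libraries (SD, n = 2). Macrophage markers rose by 0.58 over 12 members (camera adjusted p = 6.14e-10; adjusted p = 0.29 with an estimated correlation), 10 of them higher adjusted over the list alone and 0 over all genes. Lyz2, lysozyme, gave 0.82 (SE 0.156). Interferon response genes had a median of 0.39 (camera adjusted p = 0.000496; adjusted p = 0.214 with an estimated correlation; fry adjusted p = 0.0233), with 0 of 16 passing adjusted over the list alone or over all genes. Cell cycle genes had a median of 0.26 (camera adjusted p = 0.0144; adjusted p = 0.321 with an estimated correlation), with 3 of 16 higher adjusted over the list alone and 0 over all genes. Mki67, a proliferation marker, gave 0.60 (SE 0.158). The cell cycle call was lost without heterozygous replicate 2 (adjusted p = 0.115) and without homozygous replicate 2 (adjusted p = 0.0539). With a term for the label numbers the cell cycle (0.40, adjusted p = 0.128) and macrophage calls (0.23, adjusted p = 0.0864) were lost. The macrophage median was 0.37 without homozygous replicate 3 and the interferon median 0.25 without homozygous replicate 2.

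Adventitial fibroblast markers had a median of 0.31 (camera adjusted p = 0.00636; adjusted p = 0.324 with an estimated correlation) and Schwann cell markers 0.51 (adjusted p = 0.0142; adjusted p = 0.487 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Erythrocyte markers had a median of -2.53 over 5 members (camera adjusted p = 0.000113; adjusted p = 0.321 with an estimated correlation), all lower adjusted over the list alone and 0 over all genes. Hbb-bs, a beta-globin that shares 62.6% of its words with other genes, stood at 19.96, 163 and 45.4 CPM in the heterozygous and at 12.8 and 17.8 CPM in the homozygous libraries. Heat shock genes had a median of -0.44 (camera adjusted p = 0.0429; adjusted p = 0.536 with an estimated correlation), with 0 of 12 passing adjusted over the list alone or over all genes. Endothelial markers (-0.07, adjusted p = 0.83), mural (pericyte) markers (-0.06, adjusted p = 0.524) and lymphocyte markers (0.32, adjusted p = 0.367) did not pass camera. The heat shock call was lost without heterozygous replicate 2 (-0.17, adjusted p = 0.502), heterozygous replicate 3 (-0.12, adjusted p = 0.12) or homozygous replicate 2 (-0.37, adjusted p = 0.268). The Schwann cell call was lost without heterozygous replicate 3 (0.30, adjusted p = 0.0857) or homozygous replicate 2 (0.29, adjusted p = 0.371). The fibroblast median was 0.19 without heterozygous replicate 3 and 0.17 without homozygous replicate 3, and the erythrocyte median was -1.43 without heterozygous replicate 2. Without homozygous replicate 2, lymphocyte (0.85, adjusted p = 0.0115) and endothelial markers (-0.57, adjusted p = 1.17e-07) passed, while the lymphocyte median was 0.12 without homozygous replicate 3. Endothelial markers passed in the other direction without homozygous replicate 3 (0.48, adjusted p = 0.000667), where the lone homozygous library is assumed to vary like the others. The adrenal cortex, epithelial and mesothelial lists had 2, 3 and 4 tested members, too few for camera, with medians of 0.23, -1.07 and -0.42.

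**Figure D2:**
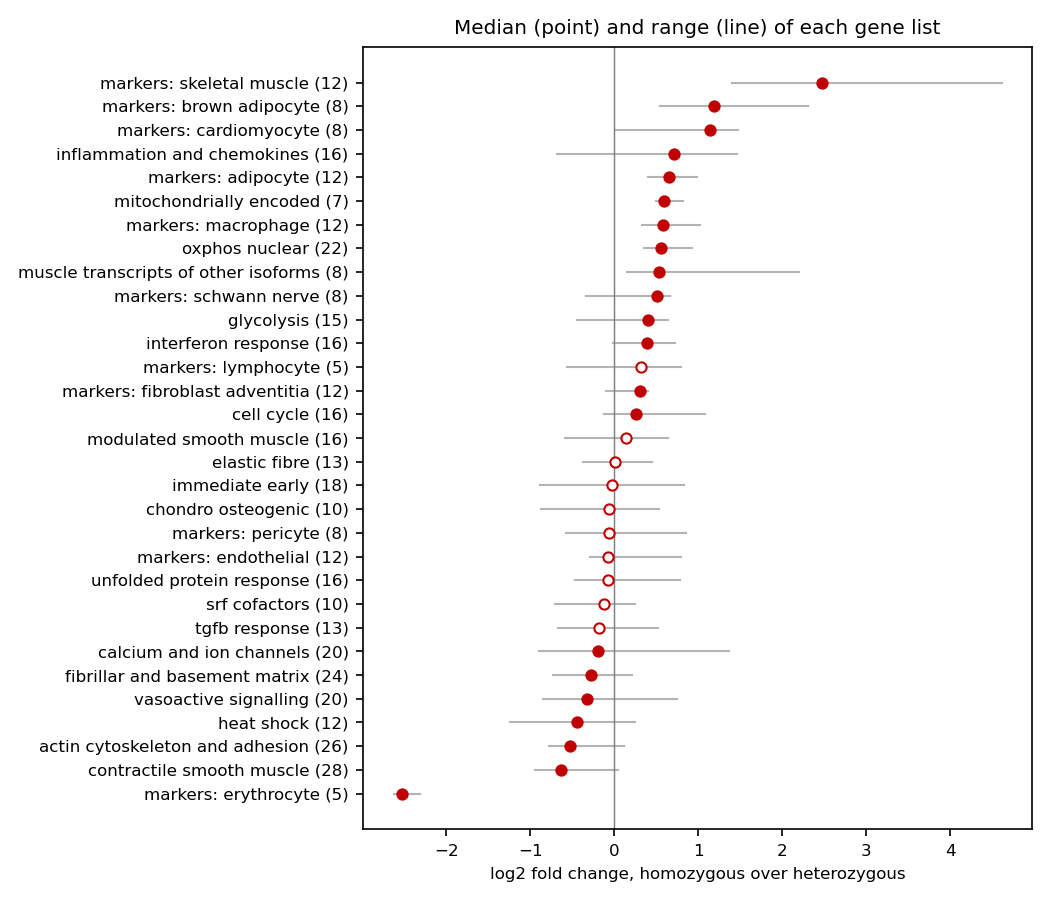
Points give each list's median log2 fold change, homozygous over heterozygous, and lines the range of its members, with the number tested in brackets; filled points passed camera at a preset correlation of 0.01. The contractile list at -0.63 is the list whose call also held with an estimated correlation.

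**Figure D3:**
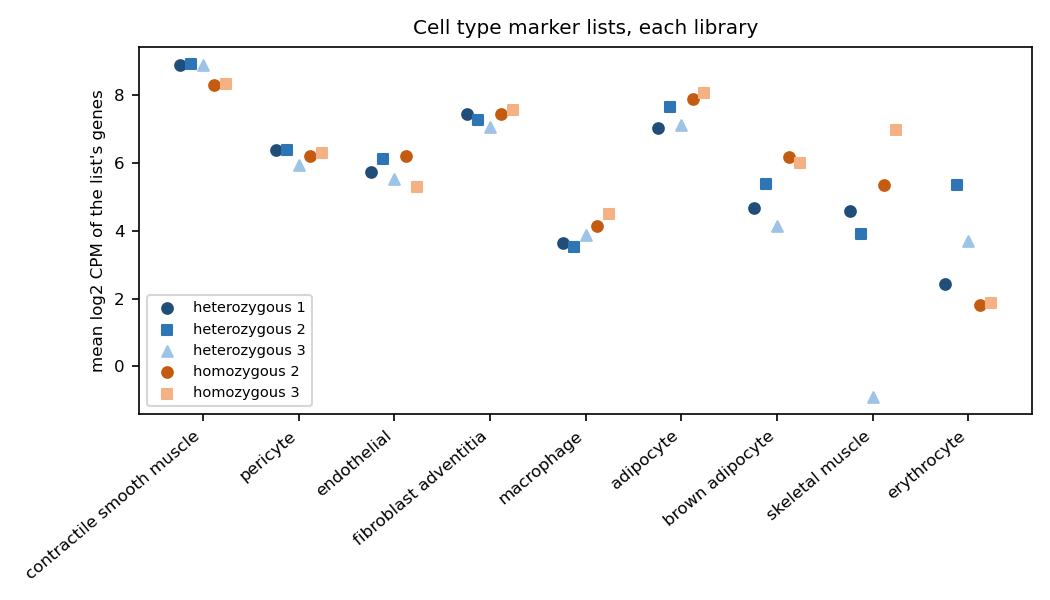
Each point is the mean log2 CPM of a marker list in 1 library. Contractile genes lie lower in both homozygous libraries than in every heterozygous library, while skeletal muscle markers also spread widely among the heterozygous libraries.

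Across single genes, edgeR called 0 higher and 0 lower at an adjusted p under 0.05, with a lowest adjusted p of 0.104. At an unadjusted p under 0.05 it gave 1644 higher and 1228 lower, 2872 in all against 910 by chance, and 1545 in all without homozygous replicate 3. DESeq2 called 524 higher and 411 lower, and limma-voom 0 higher and 1 lower. edgeR with no low-count filter called 982 higher and 432 lower. Without heterozygous replicate 2 edgeR called 139 higher and 9 lower, and without homozygous replicate 3 it called 1 higher and 0 lower. All 934 DESeq2 calls that edgeR also tested had an edgeR unadjusted p under 0.05 and groups that did not overlap. Groups did not overlap for 35.6% of the genes tested, against 20% by chance. Both chance values are averages. Where many genes move together, as with shared tissue differences, a single split of the libraries can lie far from them.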

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

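The contractile median kept its direction and camera call under every alternative, from -0.67 to -0.57. With each library left out in turn, the genes called by edgeR ranged from 0 to 139 higher (139 without heterozygous replicate 2, 1 without homozygous replicate 3) and from 0 to 9 lower. With the homozygous group reduced to a single library, that library is assumed to vary like the others. DESeq2 called 524 higher and 411 lower and limma-voom 1 lower. With no low-count filter edgeR called 982 higher and 432 lower; the prior degrees of freedom were then 29.5 instead of 4.01. A term for the label numbers, with 1 residual degree of freedom, gave 8 higher and 1 lower. Other scalings, the stricter filter, omission of mitochondrial genes, and the settings added after the data were seen called 0. Srf gave -0.59 with DESeq2 (adjusted p = 0.00373) and -0.57 with no filter (adjusted p = 0.00415), both past the threshold. Over all alternatives 62 list calls were lost (2 with a change of sign) and 12 gained (5 with a change of sign); DESeq2 called 104 and the fit with no filter 123 of the named genes. Many of these genes had been named for a DESeq2 call or a low p within a list, which partly fixes those counts. Over all 15741 genes it tested, DESeq2 called the 524 and 411 given above. The actin list stayed at -0.53 but lost its call with an estimated correlation (adjusted p = 0.214).

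The replicate block, on the 4 libraries whose number occurs in both groups, gave 3 higher and 2 lower genes and a Srf log2 fold change of -0.67. Same-numbered libraries deviated with a correlation of -0.13. With 2 libraries per group both pairs must give the same value, so it cannot show whether the numbers pair animals. The numbers were not taken to pair the samples, since the labels do not say so. A crossed pairing, added after the data were seen, called 0 higher and 0 lower. Under the block Ryr2 turned to -0.092, Malat1 to -0.028, the chondro-osteogenic median to 0.028 and the mural median to 0.027. The block leaves out heterozygous replicate 1, the lowest heterozygous library for Ryr2 (346 CPM) and Malat1 (21344 CPM), which moves both genes that way. The cause was not otherwise tested. Under the block Guca1b, Hbb-bt and the TGF-beta list (adjusted p = 0.0311) gained a call, and no other list or named gene changed its call.

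Other settings changed signs too. With the label number term, Col3a1 gave 0.17, Ryr2 -0.26, Myh6 -0.97, Vwf 0.56 and Malat1 -0.037. These are differences between homozygous replicate 2 and heterozygous replicate 3 alone, such as 4130 against 3665 CPM for Col3a1. In that fit the list medians were 0.24 for chondro-osteogenic, 0.66 for endothelial (adjusted p = 2.86e-06), 0.19 for mural and 0.18 for unfolded protein response genes. The chondro-osteogenic median was 0.017 with DESeq2 and 0.029 with no filter. The immediate-early median was 0.033 with library totals, 0.0097 with limma-voom and 0.0056 with the stricter filter. The cause of these changes with tool, scaling or filter was not tested.

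Over the fits that left out 1 library, values ranged from -0.28 to 0.019 for Pcna, -0.11 to 0.22 for Ryr2, -0.53 to 2.21 for Myh7, -0.81 to 0.050 for Rgs5, -0.20 to 0.053 for Mcl1 and -1.80 to 0.48 for Vwf. They ranged from -4.18 to 0.000248 for Msln, -0.038 to 0.16 for Malat1, -0.59 to 0.45 for Gm26917 and -0.35 to 0.37 for Des. List medians ranged from -0.15 to 0.026 for chondro-osteogenic, -0.042 to 0.052 for elastic fibre, -0.091 to 0.041 for immediate-early, -0.030 to 1.73 for cardiomyocyte and -0.57 to 0.48 for endothelial genes. They ranged from -0.14 to 0.015 for mural genes, -0.091 to 0.93 for muscle isoforms and -0.15 to 0.20 for unfolded protein response genes. In data simulated with independent genes, edgeR recovered 3 and DESeq2 16 of 50 genes changed 1.5-fold.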

Other observations

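The tests of the share of smooth muscle cells and of skeletal muscle, fat and brown fat were chosen after the results were seen, as were the interval in the last paragraph and the genes of this paragraph and the next. Fasn, Thrsp and Acaca, from a list of 12 lipogenic genes drawn up after values had been seen and so no test of a rise, stood higher in both homozygous libraries than in every heterozygous one. Fasn, fatty acid synthase, stood at 4764 ± 736 CPM in heterozygous (SD, n = 3) and 8970 ± 111 in homozygous libraries (SD, n = 2). Thrsp gave 1.15 (SE 0.194) and Acaca, acetyl-CoA carboxylase, 0.87 (SE 0.161), though Acaca shares 42.8% of its words with other genes. Srebf1, a transcription factor of lipid synthesis, gave 0.17 (SE 0.172), with libraries of the 2 groups overlapping.

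Among the largest changes that DESeq2 called, Cdh6, a cadherin, gave -1.13 (SE 0.143), Enah, an actin regulator, -1.10 (SE 0.239) and Bves -0.96 (SE 0.122). Mybpc2, a fast skeletal myosin-binding protein, gave 1.82 (SE 0.332) and Orm1, an acute-phase protein, 1.26 (SE 0.173). Mybpc2 stood at 14.0, 11.3 and 9.35 CPM in the heterozygous and at 24.9 and 57.1 CPM in the homozygous libraries. Guca1b, a guanylate cyclase activator (GRCm38 chromosome 17, 47385393 to 47392967), had 61, 77 and 68 counts in heterozygous and 0 and 0 in homozygous libraries. It was at least 21.6-fold lower against a floor of 3 counts per library, and it was the 1 gene limma-voom called. Several mitochondrial genes were counted at or near 0 in every library, among them mt-Co2 and mt-Co3, of whose 100-base words 99.5% and 99.9% occur in other annotated genes. Of those of mt-Atp8, at 0 too, 0% do, and of those of mt-Nd4, with at least 11708 counts in each library, 60.8% do.

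The contractile list was lower in the homozygous libraries. A trend with GC content or transcript length is argued against by a median of -0.671 after that trend was removed, below each of 10000 random lists matched on expression. No single library carried it, since the smallest median with 1 library left out was -0.611. The groups' contractile minus mural means differed by -0.606 (pooled SD 0.204) and did not overlap, which leaving a library out could not change. Of 10 leave-one-out differences, 9 were over 2 SD. They reuse the same libraries and overlapping mural genes, so they are not independent. The exception was -0.386 (pooled SD 0.233) over the 6 mural genes at 10 CPM or more, without homozygous replicate 3. These 6 had a median of -0.133 (SD 0.259), with Cspg4 alone near the contractile median (-0.58, SE 0.118). With every library kept, the difference over these 6 was -0.433 (pooled SD 0.194). The mural genes are pericyte markers, taken here to be made by aortic smooth muscle too, which was not tested. Only under that premise do both full differences go against a lower share of smooth muscle cells as the whole cause. With the exception above and the premise untested, a lower share cannot be told apart from loss of the second Srf copy. No test here separates that loss from the groups.

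Markers of skeletal muscle, fat and brown fat were higher in the homozygous libraries. Of 12 skeletal muscle markers, 10 put the 5 libraries in the same order, and the heterozygous libraries differed 79.3-fold in the median marker, so unequal amounts of that tissue may account for their difference. For lipogenic genes minus adipocyte markers, the difference of mean log2 CPM between groups was 0.131 (pooled SD 0.205). By library these values were 1.22, 0.755 and 0.81 in the heterozygous and 1.06 and 1.06 in the homozygous group. The small difference thus rests on heterozygous replicate 1, and the other heterozygous libraries lie below both homozygous ones. Unequal amounts of fat may account for the lipogenic rise, but these values cannot decide whether as the whole cause. Within groups the respiratory-chain and brown adipocyte lists put 3 of 4 pairs of libraries in the same order. The exception was the homozygous pair, nearly tied in the respiratory-chain mean (a gap of 0.00101). These pairs are too few to decide, so brown fat as a source of the rise in respiratory-chain genes cannot be told apart from others. A change in smooth muscle metabolism through Srf stays open and was not tested.

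Guca1b lies 0.837 Mb from Srf, so alleles that travel with the floxed allele were considered; its values and those of H2-T24 had been seen before the test. Within 10 Mb of Srf, 7 of 139 genes had an unadjusted p under 0.01, a share 0.891 times that elsewhere (Fisher's exact p = 1, two-sided; 95% odds ratio interval 0.348 to 1.88). H2-T24 (1.06, SE 0.202) and H2-T10 (0.901, SE 0.219), 10.5 and 10.4 Mb away, lay outside that window and were not among the 139. Linked alleles cannot be told apart from the loss of Srf, since that interval is wide and the design ties both to the groups.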
